A study of Sus scrofa with 24 samples.

How the data were processed

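RNA was sequenced from the ileum and the colon of sows at gestation day 114. Per the labels the sows received 1 of 4 diets from breeding on: a low-fibre diet with 3.73% crude fibre (LF), the same diet with 0.05% N-carbamylglutamate (LN), a high-fibre diet with 7.46% crude fibre (HF), and the high-fibre diet with 0.05% N-carbamylglutamate (HN). N-carbamylglutamate, here NCG, is an analogue of N-acetylglutamate, the activator of carbamoyl phosphate synthetase 1. The trial held 100 sows per diet, and 3 libraries per diet and tissue were sequenced, 24 in all. The labels do not say that the 3 libraries of a group come from separate sows, so every p-value measures the spread between libraries as labelled. They also do not say whether ileum and colon libraries come from the same sows, and the model of all 24 libraries treats them as separate. Poly(A) RNA was captured with oligo(dT) beads, primed with random primers, amplified and sequenced in paired-end mode.

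Per the labels the authors used fastp 0.22.0, HISAT2 2.1.0 and HTSeq 0.9.1 with the pig genome build Sscrofa11.1, and no settings were given. The deposited table holds counts: raw, whole read counts per gene and library, with no normalization, for 20674 genes. It also holds deposited FPKM values, made by the authors by scaling counts by gene length and library total. They follow from the counts to a relative difference of at most 2.10e-07, so they carry no further information and were not used. The deposited gene length is another unit, in bases (per the file headers), and was used only to examine trends with length. Of its values 37.3% are multiples of 3, so it is not a coding length. All 20674 genes were matched to the RefSeq annotation of Sscrofa11.1 by gene ID, and 20663 have the same start and end there. Of the genes 4137 have a locus number in place of a symbol, and 54 rows share a symbol with another gene.

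Counts were analysed in R 4.3.3 with edgeR 4.0.16. Each tissue had its own model of 4 diet means, and all 24 libraries had a model of 8 group means for the comparisons between tissues. Genes with low counts were removed with filterByExpr, libraries were scaled by TMM, and quasi-likelihood F-tests were used. Every adjusted p is a Benjamini-Hochberg value with a threshold of 0.05, from edgeR for genes and from camera of limma 3.58.1 for gene lists unless another tool is named. With no difference at all, about 755 of 15103 ileum genes would have an unadjusted p under 0.05. The same number is 754 of 15075 in the colon and 784 of 15675 in the model of all 24 libraries. Unadjusted counts near or below these show no excess. CPM values are TMM-normalised read counts scaled to the library size, and log2 CPM used a prior count of 2. The square root of the common dispersion was 0.461 in the ileum and 0.472 in the colon. Within each tissue the comparisons were the average effect of fibre, the average effect of NCG, their interaction, and HF, LN and HN each against LF. Between tissues they were colon against ileum and the differences of the fibre effect and of the NCG effect (colon minus ileum). The comparisons, tests, lists and the rule for naming genes were fixed before the data were examined.

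Library totals lay between 11951729 and 19896941 counts in the ileum and between 14843272 and 18575695 in the colon. A count of 0 in a library allows up to 3 counts, which is 0.151 to 0.251 CPM in the ileum and 0.162 to 0.202 CPM in the colon. Floors of this kind cover counting error only. Power was tested on simulated data made from the same libraries with 200 changed genes, 100 per fold size. With a 2-fold change 28% were called for NCG in the ileum, 3% for HN against LF in the ileum, 16% for NCG in the colon and 2% for HN against LF in the colon. With a 4-fold change the shares were 85%, 59%, 77% and 44% in that order. False calls numbered 5 of 14734, 2 of 14720, 5 of 14704 and 3 of 14707 unchanged genes. A further set of genes, raised less for a list test, was left out of these counts. Each gene was drawn independently around a common mean. Differences that many genes share between real libraries are therefore absent, and these shares and counts do not cover them.

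Named genes follow a fixed rule. For fibre, NCG and HN against LF these are the 10 higher and 10 lower genes with the smallest adjusted p among those past 0.05 with a mean log2 CPM above 0, with both simple effects of an average in the same direction. Where fewer than 5 passed in a direction, the 5 with the smallest p are given as values. For HF and LN against LF the 3 each way past 0.05 are given, and for the interactions and tissue differences the 5 with the smallest adjusted p. For colon against ileum the 10 each way with the largest fold among genes whose 12 and 12 libraries do not overlap are given. CPS1, OTC, ASS1, ARG2, NAGS, AKT1 and PIK3CA are given in every main comparison in which they were tested, and OTC did not pass the filter on counts in the colon. From each list described, up to 4 members with the smallest p are given. Unnamed genes and antigen receptor segments are counted and not named. A symbol stored as a date was read from its deposited description as septin 12. Some genes that these rules would name are counted in the totals and not reported here.

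The 49 fixed lists cover pathways and cell type markers. The pathway lists are arginine and urea cycle, PI3K-Akt core, PI3K-Akt growth factors and receptors, extracellular matrix and integrins, short-chain fatty acid transport and sensing, fatty acid oxidation and PPARA targets, lipid absorption and lipoproteins, cholesterol and fatty acid synthesis, bile acid transport and xenobiotic, carbohydrate and peptide digestion and uptake, tight and adherens junctions, goblet cell and mucus, epithelial antimicrobial defence, inflammatory cytokines and chemokines, interferon-stimulated genes, antigen presentation, cell cycle, oxidative phosphorylation, mitochondrially encoded, antioxidant response, unfolded protein response, immediate early genes, heat shock, circadian clock, and steroid and glucocorticoid response. The marker lists are enterocyte, goblet, enteroendocrine, tuft, stem and crypt, T and NK, B cell and follicle, plasma cell, macrophage and dendritic, neutrophil, mast cell, smooth muscle, fibroblast, endothelial, enteric neuron and glia, interstitial cells of Cajal, adipocyte and mesothelium, erythrocyte, pancreas acinar, liver, skeletal muscle, reproductive tract, ileum identity and colon identity. A list needed 5 measured members. The erythrocyte, pancreas acinar and liver lists had fewer and were not tested, the skeletal muscle list reached 5 only in the model of all 24 libraries, and the reproductive tract list was not tested in the colon alone.

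Lists were tested with camera at a preset correlation between genes of 0.01. Beside it stand camera with an estimated correlation and fry, whose p-value asks whether the genes of a list move one way on balance and whose mixed p-value asks whether they change in either direction. The 267 tests of 45 lists in the 6 main comparisons were adjusted together, and so were 227 tests of 46 lists in the interactions and tissue comparisons. For each list the number of called members is given over all genes and adjusted over the list alone. Enrichment was tested with a one-sided hypergeometric test (Fisher's exact test) against all tested genes with an annotation, and repeated with the length trend removed. Permutation tests are two-sided.

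The alternatives fixed in advance were the RLE size factors, no filter on low counts, DESeq2 1.42.0, limma voom with sample quality weights, a replicate block, each library left out in turn, and only the 2 compared groups in the fit. For lists they were the estimated correlation, fry, RLE, the block and each library left out. Alternatives added after the data were seen removed each library's trend with gene length by a lowess fit (span 0.3), used the mean of the smooth muscle markers or of these and the enterocyte markers as covariates, left out the ileum libraries with FABP6 above 500 CPM, or left out the 2 colon libraries with the lowest enterocyte markers. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.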

Results

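Gene expression was measured by RNA sequencing in the ileum and colon of sows fed diets that differed in crude fibre and in NCG. Each of the 8 groups of tissue and diet (LF, LN, HF and HN in ileum and in colon) had 3 libraries, so each tissue had 12. Total counts per library lay between 11951729 (ileum HN 1) and 19896941 (ileum LF 1), and between 16309 and 16983 genes were detected per library. The 10 most abundant genes took 7.37% to 16.0% of the counts of a library, and mitochondrially encoded genes took 4.96% to 9.97%. Between replicates the correlation of log2 CPM lay between 0.697 and 0.979.

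In the ileum a large set of genes was higher with NCG in the average over the 2 fibre levels. A batch or a difference in RNA quality that follows NCG has no label, so these are differences with the diet label. PGAP1, which removes an acyl chain from the GPI anchors of membrane proteins, averaged 24.8 ± 2.11 CPM with LF, 155 ± 22.2 with LN, 45.3 ± 5.39 with HF and 107 ± 27.4 with HN (mean ± SD, n = 3). LTN1, the ubiquitin ligase of stalled ribosomes, averaged 10.9 ± 1.40, 48.5 ± 11, 19.0 ± 0.382 and 37.8 ± 3.48 CPM in the same order. PPIP5K2, an inositol pyrophosphate kinase, averaged 6.56 ± 1.85, 42.6 ± 11.4, 12.7 ± 1.26 and 30.8 ± 2.62 CPM. TINAG, a basement membrane protein, fell from 38.4 ± 14.7 CPM with LF to 8.02 ± 3.62 with LN, and averaged 29.3 ± 6.91 with HF and 15.3 ± 4.99 with HN. MAGOH, a core protein of the exon junction complex, averaged 32.3 ± 2.0, 21.4 ± 2.19, 35.3 ± 5.77 and 23.4 ± 1.93 CPM in the order LF, LN, HF and HN.

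**Figure D1:**
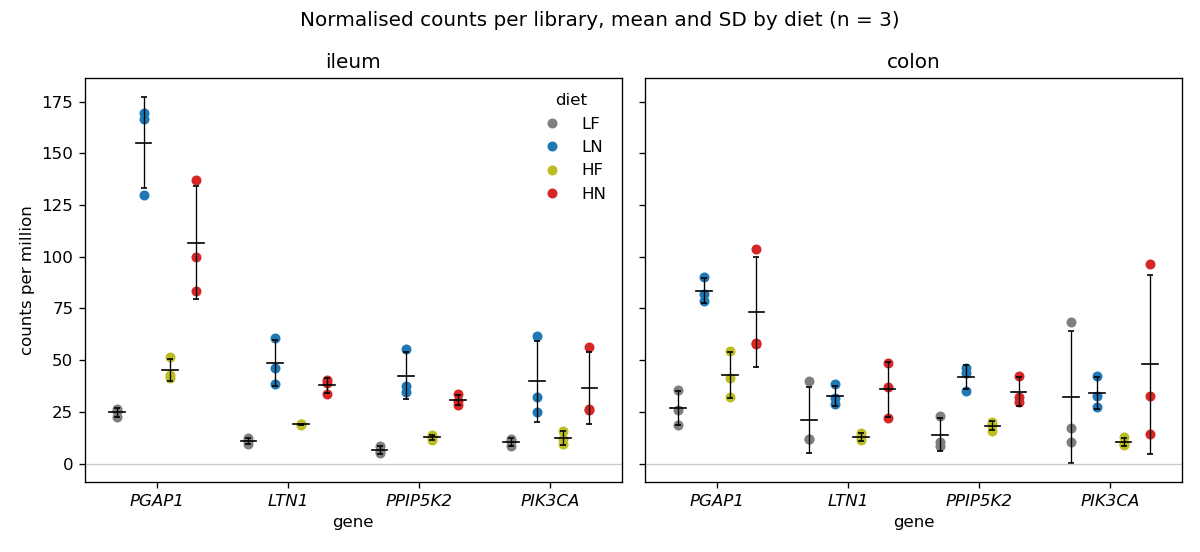
Normalised read counts in CPM (vertical axis, linear) of PGAP1, LTN1, PPIP5K2 and PIK3CA in each library of the ileum (left) and the colon (right), coloured by diet; points are libraries, bars are the mean and SD of n = 3. In the ileum the PGAP1 mean was 24.8 with LF and 155 with LN.

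Averaged over the fibre levels, 884 of 15103 tested ileum genes passed with NCG, 819 higher and 65 lower, and 3251 had an unadjusted p under 0.05. PGAP1 (gene 100620753, Sscrofa11.1 chromosome 15, 100733552 to 100820603) rose by 1.94 ± 0.15 on the log2 scale (± SE; adjusted p = 0.0014). LTN1 (gene 106505847, chromosome 13, 192295764 to 192358762) rose by 1.57 ± 0.14 (adjusted p = 0.00177) and PPIP5K2 (gene 100625306, chromosome 2, 108596733 to 108690859) by 1.98 ± 0.18 (adjusted p = 0.00177). SUCO, N4BP2, PTAR1, PPP4R3B, SKIL and TMF1 rose by 1.53 to 1.91, and YTHDC2 by 1.08 (adjusted p = 0.00203). TINAG (chromosome 7, 26448612 to 26522993) fell by 1.60 ± 0.28 (adjusted p = 0.00665), MAGOH by 0.59 (adjusted p = 0.0134) and PGP by 1.02 (adjusted p = 0.0147). SNRPE, ATP6V1F, DRAP1, ADPRH, RBM42, GNPDA1 and SF3B5 fell by 0.49 to 0.71 (adjusted p = 0.0186 to 0.0243). The higher genes had a median length of 6737 bases, against 3721 for all tested genes.

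The 10 named higher genes, TINAG, MAGOH and PGP passed in each of the 12 fits without 1 library. The other 7 lower genes lost the call in some of these fits, with adjusted p between 0.0518 and 0.08. ADPRH lost it without HN 1, HF 1, LN 3 or LF 2, and ATP6V1F without HN 1, HF 1, LN 2 or LF 1. DRAP1 lost it without HF 1, HF 3, LN 2, LF 2 or LF 3, and GNPDA1 without HN 1, HF 1, HF 3, LN 2, LF 2 or LF 3. RBM42 lost it without HN 1, HF 1, LN 2 or LF 3, SF3B5 without HF 1, HF 3, LN 2, LN 3, LF 2 or LF 3, and SNRPE without HF 1, HF 3, LN 2 or LF 2. Without the 3 libraries high in FABP6 the adjusted p was 0.0528 for TINAG, 0.0608 for MAGOH and 0.128 for PGP, and with the length trend removed it was 0.124 for MAGOH. ATP6V1F, DRAP1, RBM42 and SNRPE lost the call in both of these settings (0.0568 to 0.249), and ADPRH (0.0518) and GNPDA1 (0.0732) without the 3 libraries. The count of 884 became 514 without HF 1, 541 without HF 3 and 550 without LF 2, and it was 1739 with DESeq2, 1835 with voom and 1736 with the smooth muscle and enterocyte marker means as covariates.

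Members of the PI3K-Akt lists were among the genes that rose in the ileum with NCG. The series title names this pathway, so the list may have been chosen on these samples and is not independent evidence. PIK3CA, the catalytic subunit of PI3K (gene at chromosome 13, 117193935 to 117282151), rose by 1.73 ± 0.29 (adjusted p = 0.00557), from 10.6 ± 1.90 CPM with LF to 39.8 ± 19.5 with LN and from 12.5 ± 3.26 with HF to 36.5 ± 17.5 with HN. RICTOR, a subunit of the mTOR complex that phosphorylates AKT, rose by 2.05 (adjusted p = 0.0022), the S6 kinase RPS6KB1 by 0.95 (adjusted p = 0.0029) and the growth factor IGF1 by 1.64 (adjusted p = 0.012). The log2 change of AKT1 was −0.35 (adjusted p = 0.143). In all, 5 of the 40 core members rose over all genes. PIK3CA, RICTOR, RPS6KB1 and IGF1 kept the call in the 12 single omissions. Adjusted over the list alone 5 rose and 3 fell. As a group the core list did not pass camera (adjusted p = 0.811).

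Among other lists in the ileum, the integrins ITGB8 and ITGAV rose with NCG by 2.12 and 1.11, 2 of the 39 matrix and integrin genes (camera adjusted p = 0.877). SLC16A7, a monocarboxylate transporter, rose by 1.17, the aryl hydrocarbon receptor AHR by 1.19 and the mucin glycosyltransferase C1GALT1 by 0.93, each the only called member of its list. NR1D2, DBP and PER3 of the circadian clock rose by 1.44, 1.43 and 0.61, 3 of 18, with 4 adjusted over the list alone (camera adjusted p = 0.0803). Of 37 PI3K-Akt growth factors and receptors, HGF, KITLG and ANGPT1 rose by 2.49, 0.86 and 1.97 (camera adjusted p = 0.325). Antioxidant genes GCLM, SLC7A11 and NFE2L2 rose by 1.37, 1.77 and 1.33, 3 of 23, with 3 higher and 1 lower adjusted over the list alone. HSPA6 rose by 0.96, PROX1 by 0.84 and mitochondrial ND2 by 1.05, each the only called member of its list, and heat shock had 2 higher and 1 lower adjusted over the list alone. ITGB8, ITGAV, SLC16A7, AHR, C1GALT1 and NR1D2 kept the call in the 12 single omissions.

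The other circadian, growth factor, antioxidant, heat shock, endothelial and mitochondrial genes named for NCG lost the call without 1 library. DBP lost it without HF 3 (0.0513) or LF 2 (0.0575), and GCLM without HF 3 (0.0636), LF 2 (0.0573) or LF 3 (0.0571). HGF lost it without HN 1, HF 1, HF 3, LF 2 or LF 3 (0.0549 to 0.0802), and SLC7A11 without HN 2, HF 1, HF 3, LF 2 or LF 3 (0.0546 to 0.074). HSPA6 lost it without HN 1, HF 1, HF 3, LN 3, LF 2 or LF 3 (0.0508 to 0.0779), and KITLG without HN 1, HN 2, HF 1, HF 2, LN 3, LF 1 or LF 2 (0.0503 to 0.0937). NFE2L2 lost it in all omissions but those of HN 2, HN 3, HF 3 and LN 2 (0.058 to 0.115), ANGPT1 in all but those of LN 1, LN 2 and LN 3 (0.0676 to 0.101), and ND2 in all but those of HN 2 and LN 2 (0.0554 to 0.0957). PER3 lost it in all but those of HN 2, LN 1 and LF 1 (0.0536 to 0.0975), and PROX1 in all but those of HN 3, HF 2 and LN 1 (0.0622 to 0.115). With the length trend removed ANGPT1 had 0.0502, KITLG 0.0599, SLC16A7 0.068, PROX1 0.0945, NFE2L2 0.113 and PER3 0.306. Without the 3 ileum libraries high in FABP6 NFE2L2 had 0.0611, IGF1 0.0756, HGF 0.101, PROX1 0.102, ND2 0.116, KITLG 0.128 and ANGPT1 0.18. ND2 also had 0.0662 with voom, and NFE2L2 0.0508 with the smooth muscle covariate.

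The enzymes around the target of NCG did not pass in the ileum. Log2 changes with NCG were −0.58 for CPS1, which makes carbamoyl phosphate, −0.02 for OTC, −1.83 for ASS1, −0.54 for ARG2 and 0.06 for NAGS (adjusted p = 0.29 to 0.987). The value of ASS1 was −0.21 without LF 1 and −0.72 without HF 2, and 0.71 without the 3 libraries high in FABP6. Of the 24 genes of the arginine and urea cycle list edgeR called 0, and camera did not call the list. Of the adipocyte markers 0 were called over all genes and 3 were higher adjusted over the list alone. The library LN 3 stood apart with 1144 CPM of ADIPOQ, 338 of PLIN1 and 2007 of FABP4, and HGF had 584 counts in LN 3 and 68 and 79 in LN 1 and LN 2.

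As groups, genes of oxidative phosphorylation fell in the ileum with NCG and interferon-stimulated genes rose. All 21 measured oxidative phosphorylation genes had negative changes, with a median of −0.38 (camera adjusted p = 0.000357), for example NDUFA2 −0.38, NDUFB10 −0.47 and NDUFV2 −0.48, and 0 of them passed alone. These genes are short (median 933 bases), and with the length trend removed the median was −0.19. Of 30 interferon-stimulated genes 25 were positive, with a median of 0.66 (adjusted p = 0.000615). IFIH1, a sensor of double-stranded RNA, rose by 2.0, from 5.65 ± 2.74 CPM with LF to 42.5 ± 15.6 with LN, and was the 1 called member, with 4 adjusted over the list alone. RSAD2, DDX58 and IFI44L did not pass, with 2.27, 1.30 and 1.35. Cell cycle genes fell (5 positive and 24 negative, for example MCM7 −0.68 and TYMS −1.06; adjusted p = 0.00265), and so did cholesterol and fatty acid synthesis (7 positive and 16 negative, median −0.58; adjusted p = 0.0254). With an estimated correlation each of the 4 calls was lost (adjusted p = 0.997 with an estimated correlation), and none passed fry (adjusted p = 0.938 to 0.959). Differences of list means with NCG had an exact permutation p of 0.0628 for oxidative phosphorylation, 0.0931 for interferon-stimulated genes and 0.359 for cell cycle. None of these passed (adjusted p = 0.495 to 0.778 over 52 such tests). The cell cycle mean was 1.73 in LN 3 and 3.80 to 5.43 in the other ileum libraries, and this call was lost without LN 3 (0.0827), and the cholesterol call without HN 2 (0.11), HF 1 (0.0501), LN 2 (0.122) or LF 1 (0.116).

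With NCG added to the low-fibre diet alone 640 ileum genes were higher and 16 lower, so that LN against LF called 656 of 15103 genes, with 2925 at an unadjusted p under 0.05. PGAP1 rose by 2.64 (adjusted p = 0.0022), LTN1 by 2.15 and PPIP5K2 by 2.69 (adjusted p = 0.00276 for both). TINAG fell by 2.26 (adjusted p = 0.0108), the leukocyte receptor CD300A by 1.97 (adjusted p = 0.0244) and ADPRH by 0.77 (adjusted p = 0.0294). CD300A lost the call without LN 1 (0.0703), LN 3 (0.103), LF 1 (0.0741) or LF 2 (0.0819), and ADPRH without HF 3 (0.0534), LN 1 (0.0724), LN 3 (0.117), LF 1 (0.0834), LF 2 (0.105) or LF 3 (0.074). The count became 133 without LF 2, 282 without LF 3 and 395 without LN 3, 0 with only the 6 libraries of both groups in the edgeR fit, 1067 with both marker covariates, 1573 with DESeq2 and 1727 with voom.

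Both supplements together were compared with the reference diet in HN against LF, and 284 ileum genes passed, 283 higher and 1 lower (1985 at an unadjusted p under 0.05). PGAP1, LTN1, PPIP5K2, YTHDC2, N4BP2 and PHC3 rose by 2.1, 1.79, 2.22, 1.35, 2.12 and 2.12 (adjusted p = 0.0159 each). PPP4R3B, DENND4A and PTAR1 rose by 2.02, 1.5 and 1.91, and ZNF146 by 1.73 (adjusted p = 0.0204). RICTOR and RPS6KB1 rose by 2.22 and 1.0, 2 of the PI3K-Akt core genes, with 4 adjusted over the list alone (camera adjusted p = 0.78). ITGB8, AHR, C1GALT1 and IFIH1 rose by 2.24, 1.36, 1.0 and 2.05, the only called members of their lists. PPP1R3B, a glycogen-targeting subunit of protein phosphatase 1, was the 1 lower gene, at 60.8 ± 9.22 CPM with LF and 34.5 ± 3.22 with HN (log2 change −0.82, adjusted p = 0.0494).

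Values just short of the threshold in HN against LF were a log2 change of −1.31 for PGP (adjusted p = 0.052), −3.06 for FAM46B (0.0559) and −0.59 for LRPAP1 (0.0644), and 1.79 for PIK3CA (0.0573). ACTA1, skeletal muscle actin, averaged 48.3 ± 69.7 CPM with LF and 0.0201 ± 0.0348 with HN (adjusted p = 0.0623). CPS1, ASS1, AKT1, OTC, ARG2 and NAGS had −0.48, −2.67, −0.44, 0.22, 0.26 and 0.05 and did not pass. The 284 calls became 0 without HN 2, LF 1, LF 2 or LF 3, and 1 (PGAP1) without HN 1. They became 98 without HF 1, 103 without HF 3, 162 without LN 1, 176 without HF 2, 480 without LN 3, 0 with only the 6 libraries of both groups, 0 without the 3 ileum libraries with FABP6 above 500 CPM, 189 with the length trend removed, 88 with both marker covariates, 896 with DESeq2 and 495 with voom. RICTOR and ITGB8 had adjusted p = 0.0531 to 0.135 without any of HN 1, HN 2, LF 1, LF 2 or LF 3, and RPS6KB1, AHR, C1GALT1 and IFIH1 lost the call without any of these 5 (0.0531 to 0.216) and without HF 1 or HF 3 (0.0554 to 0.0872). C1GALT1 and IFIH1 lost it without HF 2 or LN 1 as well (0.0616 to 0.079). PGAP1 had adjusted p = 0.0662, 0.0531, 0.0728 and 0.0893 without HN 2, LF 1, LF 2 and LF 3, and PPP1R3B lost the call in all single omissions but that of LN 3 (0.0514 to 0.194). The other higher genes named for HN against LF lost the call without HN 1 as well (0.0648). PPP1R3B also lost it with RLE (0.0572), no filter (0.0607), voom (0.0945) and both marker covariates (0.175). With both marker covariates ZNF146 had 0.0506, RICTOR 0.0681, ITGB8 0.0745, RPS6KB1 0.088, AHR 0.136, IFIH1 0.146 and C1GALT1 0.159. With the length trend removed C1GALT1 had 0.132 and IFIH1 0.0582, and IFIH1 had 0.053 with no filter and 0.0578 with voom.

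As groups in HN against LF of the ileum, oxidative phosphorylation fell (21 of 21 negative, median −0.49; camera adjusted p = 8.93e-05) and smooth muscle markers fell (17 of 17 negative, median −2.69; adjusted p = 0.000186). The smooth muscle mean was 6.70, 8.74 and 10.80 in LF 1, LF 2 and LF 3, and 6.07, 8.25 and 5.98 in HN 1, HN 2 and HN 3, so its size rests largely on LF 3. ACTG2, the smooth muscle actin, averaged 3655 ± 4163 CPM with LF and 276 ± 286 with HN, and TAGLN had −2.87. Interferon-stimulated genes rose (28 of 30 positive, for example GBP2 1.48 and RSAD2 2.53; adjusted p = 0.000322), as did T and NK markers (0.00518) and antigen presentation (0.0488). Fatty acid oxidation (HADHA −0.83; 0.00214), junction genes (0.0231) and cholesterol synthesis (0.0266) fell. With an estimated correlation all 8 calls were lost (adjusted p = 0.997 with an estimated correlation), and fry called none (0.938 to 1). Calls ended without HN 1 for interferon-stimulated genes (0.129), without HN 2 (0.184) or LF 2 (0.0938) for fatty acid oxidation and without HN 2 (0.0702) or LF 3 (0.34) for T and NK markers. They ended without HN 2 (0.313) or LF 1 (0.54) for cholesterol synthesis and without HN 2 (0.975, direction reversed), LF 1 (0.0626) or LF 2 (0.0553) for junctions. Antigen presentation lost its call without HN 2 (0.291), HF 3 (0.053), LN 3 (0.0635), LF 2 (0.0617) or LF 3 (0.924), and with RLE (0.0574).

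With more fibre the ileum had higher expression of cell cycle and immune cell gene groups and lower expression of smooth muscle markers. All 29 cell cycle genes were positive (median 0.45, for example TYMS 0.65 and PCNA 0.46; camera adjusted p = 2.02e-09), and their mean was 1.73 in LN 3 and 3.80 in LN 2 against 4.49 to 5.43 in the other ileum libraries. All 16 T and NK markers were positive (median 0.73, for example CD8B 0.81, CD5 0.97 and CD4 1.01; adjusted p = 3.63e-07), and 21 of 24 antigen presentation genes were positive, among them SLA-2 with 1.71 (adjusted p = 1.30e-05). The T and NK mean was lowest in LF 3 (3.41) and LN 3 (3.69) and highest in LF 1 (6.11). All 15 B cell markers were positive (CD79B 1.64, CCR7 1.87; adjusted p = 0.000621), and macrophage markers rose (0.00146). The mean over the B cell markers was 6.69 in HN 2, 5.79 in HF 2, 5.61 in LF 1 and 4.67 in HN 3, against −0.034 to 3.18 in the other ileum libraries. HN 2, HF 2 and LF 1 are also the 3 libraries high in FABP6, and no list was tested without these 3 together. All 17 smooth muscle markers were negative (median −2.0, for example KCNMB1 −2.33, PLN −2.56 and DES −2.55; adjusted p = 1.69e-06), and 14 were lower adjusted over the list alone, against 0 over all genes. Their mean was 10.80 in LF 3, 9.11 in LN 3, 8.74 in LF 2 and 8.25 in HN 2, against 5.93 to 6.70 in the other ileum libraries. The differences of these list means with fibre did not pass (exact permutation p = 0.173 for cell cycle, 0.0866 for T and NK, 0.268 for B cells and 0.113 for smooth muscle, adjusted p = 0.495 to 0.735 over 52 such tests). Lipid absorption (0.000615), fatty acid oxidation (0.00117), circadian clock (0.00367), junctions (0.00835), matrix and integrins (0.00992) and carbohydrate and peptide digestion (0.0203) fell, and inflammatory cytokines (0.00402) and plasma cell markers (0.0465) rose. With an estimated correlation all 14 calls were lost (adjusted p = 0.997 with an estimated correlation), and fry called none (0.938 to 1).

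The cell cycle, T and NK, antigen presentation, macrophage and smooth muscle calls for fibre in the ileum held in all 12 single omissions. Without HN 2 the calls ended for lipid absorption (0.195), B cells (0.0723), fatty acid oxidation (0.0946), inflammatory cytokines (0.187), junctions (0.789) and carbohydrate and peptide digestion (0.474). Other omissions that ended a call were LF 2 for fatty acid oxidation (0.0554), LF 1 for the circadian clock (0.0585), and HF 2 (0.0918) and LF 3 (0.104) for inflammatory cytokines. Junctions lost theirs without LN 1 (0.0706), matrix and integrins without LN 3 (0.287) or LF 3 (0.104), and carbohydrate and peptide digestion without LN 3 (0.0528) or LF 1 (0.394). With the smooth muscle and enterocyte marker means as covariates the log2 changes turned to −0.36 for CD4, −0.22 for CD5, −0.81 for CD79B, −0.79 for CCR7 and −0.0038 for PCNA. The plasma cell call ended without HN 1 (0.185), HN 3 (0.181), HF 1 (0.0821), HF 3 (0.186), LN 3 (0.65), LF 1 (0.262) or LF 3 (0.0662), and with RLE (0.0568).

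No single ileum gene passed for fibre with edgeR (794 of 15103 at an unadjusted p under 0.05 against 755 expected by chance, 1 gene with DESeq2, 0 with voom). The genes nearest to passing had log2 changes of 0.91 for FAM200B, 2.11 for SLITRK3, 1.22 for SLA-3, 0.69 for NFE2L3, 0.83 for HPDL, −1.01 for S100A6, −2.01 for FAM46B, −2.37 for SLC38A3, −1.86 for PC and −2.15 for AQP7 (adjusted p = 0.802 each). CPS1, OTC, ASS1, ARG2, NAGS, AKT1 and PIK3CA had 0.09, 0.24, −0.84, 0.80, −0.01, −0.09 and 0.06, and none passed. HF against LF called 0 ileum genes with edgeR (538 unadjusted, 12 with DESeq2, 0 with voom). The interaction of fibre and NCG called 0 (672 unadjusted, 20 with DESeq2, 1 with voom); the mitochondrial carrier UCP3 averaged 1.16 ± 1.07, 27.2 ± 18.1, 3.36 ± 2.20 and 0.337 ± 0.186 CPM with LF, LN, HF and HN (adjusted p = 0.453). ABCB11, the bile salt export pump, averaged 3.15 ± 0.295 CPM with LN and had 0 counts with HN, and ETNK1, TMEM176A and PGAP1 had interaction values of −1.87, −2.0 and −1.41 (adjusted p = 0.872).

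In the colon with NCG, oxidative phosphorylation and lipid synthesis genes fell as groups, but no gene passed alone. All 21 oxidative phosphorylation genes were negative (median −0.33; camera adjusted p = 2.01e-08), with 2 lower adjusted over the list alone; NDUFB5, a subunit of complex I, averaged 70.22 ± 2.93 CPM with LF, 41.4 ± 5.65 with LN, 61.1 ± 5.02 with HF and 49.8 ± 2.89 with HN. Cholesterol and fatty acid synthesis fell (1 of 23 positive; adjusted p = 0.000621), with FASN at −1.05, ELOVL6 at −1.04 and ACACA at −0.63. Both calls held in all 12 single omissions. The oxidative phosphorylation genes are short (median 933 bases), and across genes the NCG effect in the colon went with length (Spearman's rho = 0.360). The length trend was not removed for this list in the colon, so a length trend and NCG cannot be told apart there. Interferon-stimulated genes (IFIH1 1.0; 0.0136), mitochondrially encoded genes (ND4 0.65; 0.0152) and circadian clock genes (PER3 1.05, DBP 1.92; 0.0187) rose, with 2, 2 and 5 members adjusted over the list alone. Adipocyte (CIDEC −1.22; 0.0124) and endothelial markers (0.0493) fell. Differences of list means with NCG had an exact permutation p of 0.0195 for oxidative phosphorylation and 0.314 for interferon-stimulated genes. It was 0.0628 for mitochondrially encoded genes and 0.0714 for adipocytes, and none of these passed (adjusted p = 0.338 to 0.742 over 52 such tests). With an estimated correlation all 7 calls were lost (adjusted p = 0.997 with an estimated correlation), and fry called none (0.938 each). Calls ended without HN 3 (0.0803) or LF 2 (0.0865) for adipocytes and without HN 3 (0.234), LN 3 (0.168), LF 1 (0.0761) or LF 2 (0.0642) for interferon-stimulated genes. They ended without HN 2 (0.0538) or LF 1 (0.0761) for mitochondrially encoded genes and without HN 1 (0.26) or LF 3 (0.0812) for the clock. Endothelial markers lost the call without HN 3 (0.238), HF 2 (0.0802), HF 3 (0.137), LN 1 (0.0713), LN 3 (0.064), LF 1 (0.0717) or LF 2 (0.365), and with RLE (0.0566).

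For NCG in the colon edgeR called 0 of 15075 genes, with 1863 at an unadjusted p under 0.05, DESeq2 called 465 and voom 4242. Without LF 2 edgeR called 292, without HN 1 it called 2, without both libraries it called 464, and with the smooth muscle and enterocyte marker means as covariates it called 1814. The genes nearest to passing had log2 changes of 1.17 for PPP1R9A, 1.27 for LCORL, 1.29 for SMC4, 1.22 for BRWD3, 1.20 for DOCK10, −0.97 for F2RL2, −0.73 for FABP5, −1.67 for MEDAG, −1.07 for PLAC9 and −0.59 for SS18L2 (adjusted p = 0.182 to 0.191). PIK3CA and AKT1 had 1.14 (adjusted p = 0.414) and −0.20 (adjusted p = 0.525), and CPS1, ASS1, ARG2 and NAGS had 0.04, 0.68, 0.10 and −0.15. LN against LF called 0 colon genes with edgeR (2010 unadjusted), 11 without HN 1, 282 without HN 1 and LF 2, 1571 with both marker covariates, 615 with DESeq2 and 5850 with voom. Of the genes higher in the ileum with NCG 814 were tested in the colon. Their mean log2 CPM was 4.87 ± 0.39 in the 6 colon libraries with NCG and 4.04 ± 0.52 in the 6 without (exact permutation p = 0.0216, a test chosen after the ileum genes were seen).

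**Figure D2:**
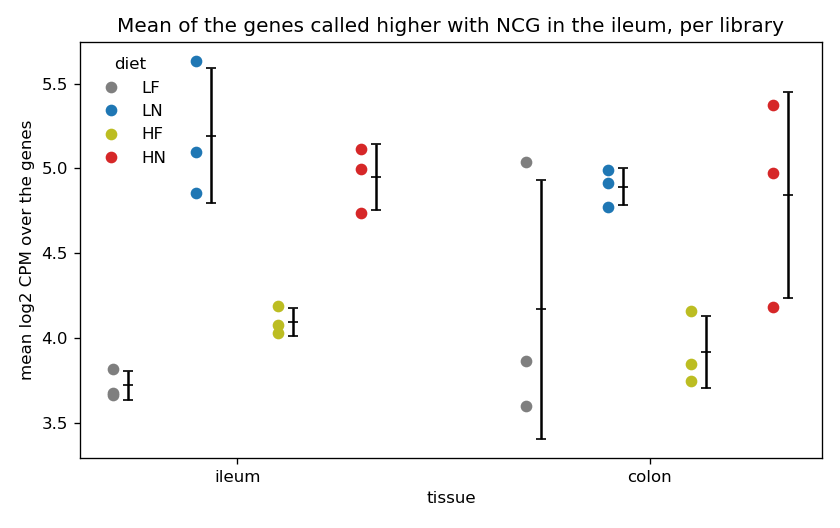
Mean log2 CPM (vertical axis) over the genes called higher with NCG in the ileum, per library, in ileum and colon, coloured by diet, with the mean and SD of n = 3. Ileum values are over all 819 genes and colon values over the 814 tested there, with each tissue scaled on its own. The ileum genes were chosen for their difference, and in the colon the diet means were 4.17 with LF, 4.89 with LN, 3.92 with HF and 4.84 with HN.

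With both supplements against the reference diet, ileum-type and absorptive genes were higher in the colon libraries and markers of the muscle wall and fat lower. Sucrase-isomaltase (SI) averaged 2.77 ± 2.32 CPM with LF and 43.7 ± 27.6 with HN, and ileum identity genes rose as a group (13 of 15 positive, median 3.07; camera adjusted p = 0.000186), with 8 higher adjusted over the list alone and 0 over all genes. The library HN 1 carried ileum transcripts: 22 of 25 ileum genes reached 0.5% of their ileum mean there, and APOB was 48.7 CPM in it against a LF mean of 0.266 ± 0.128. The ileum identity mean was 2.84 in HN 1, 0.50 in HN 2 and 1.69 in HN 3, against −0.54 to 0.27 with LF, so HN 1 adds to the size of this rise. Enterocyte markers rose (16 of 16 positive, median 1.07, ANPEP 2.74; adjusted p = 0.00117), with 3 adjusted over the list alone. Carbohydrate and peptide digestion (0.00232; 5 adjusted over the list alone), mitochondrially encoded genes (0.00399), T and NK markers (KLRK1 1.57, CCL5 1.55; 0.0149), interferon-stimulated genes (0.0192) and lipid absorption (0.0313) rose. Smooth muscle (ACTA2 −1.74; 8.93e-05), fibroblast (0.00144), adipocyte (CIDEC −2.59, FABP4 −2.35; 0.00175), oxidative phosphorylation (0.00189), endothelial (0.00678) and enteric neuron genes (0.0268) fell. With an estimated correlation all 13 calls were lost (adjusted p = 0.997 with an estimated correlation), and fry called none (0.938 to 1).

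In HN against LF of the colon the ileum identity and adipocyte calls held in all 12 single omissions. Without HN 3 the calls ended for smooth muscle (0.172), enterocyte (0.14), fibroblast (0.0928), endothelial (0.0928), T and NK (0.392), interferon-stimulated (0.367), enteric neuron (0.645) and lipid absorption genes (0.0858). Without LF 2 they ended for enterocyte (0.514), fibroblast (0.0606), carbohydrate and peptide (0.0681), endothelial (0.211), T and NK (0.798), interferon-stimulated (0.0751), enteric neuron (0.363) and lipid absorption genes (0.181). Without HN 1 they ended for oxidative phosphorylation (0.322), carbohydrate and peptide digestion (0.068), mitochondrially encoded genes (0.0654) and lipid absorption (0.0619). Other omissions that ended a call were HN 2 for T and NK (0.178), LF 1 for mitochondrially encoded (0.0717), interferon-stimulated (0.174) and enteric neuron genes (0.162), and LF 3 for oxidative phosphorylation (0.166).

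No single colon gene passed for HN against LF with edgeR (1348 of 15075 at an unadjusted p under 0.05, 183 with DESeq2, 6922 with voom, 2098 with both marker covariates). Among the nearest were log2 changes of 1.43 for PPP1R9A, 1.67 for MAP2K6, 1.71 for LCORL, 1.01 for RHOF, 1.0 for ZSWIM6, −0.92 for RCN1, −2.18 for MEDAG, −1.90 for EFHD1 and −0.86 for FABP5 (adjusted p = 0.371 to 0.389). CPS1, ASS1, ARG2, NAGS, AKT1 and PIK3CA had 2.37, 0.27, 0.19, 0.54, −0.23 and 0.58 and did not pass. CPS1 averaged 0.373 ± 0.0805 CPM with LF and 1.97 ± 2.89 with HN in the colon. It had 79 counts in HN 1, the library with ileum transcripts, and its log2 change was −0.26 without that library.

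With more fibre the colon libraries had less of the smooth muscle transcripts and more of the absorptive and mucus transcripts. ACTG2 averaged 16889 ± 9653 CPM with LF, 7145 ± 7059 with LN, 188 ± 30.3 with HF and 4861 ± 6977 with HN. All 17 smooth muscle markers were negative for fibre (median −2.34, for example ACTG2 −3.52, MYLK −2.30 and TAGLN −2.34; camera adjusted p = 2.02e-09), and fibroblast (0 of 13 positive; 0.00196), enteric neuron (0.00239), adipocyte (0.0403) and matrix and integrin genes (0.0493) fell. All 16 enterocyte markers were positive (median 0.85, ANPEP 1.49; adjusted p = 3.12e-05), and ileum identity (12 of 15 positive, median 2.09, SI 2.19; 2.44e-05), fatty acid oxidation (23 of 26 positive, HADHA 0.44; 8.93e-05) and lipid absorption (12 of 15 positive; 0.00118) rose, with 9 ileum identity and 3 lipid absorption members adjusted over the list alone. The enterocyte mean was 2.06 in LF 2 and 4.47 in HN 1, against 5.21 to 7.69 in the other colon libraries. Its difference with fibre did not pass (exact permutation p = 0.225, adjusted p = 0.713 over 52 such tests). HN 1, the library with ileum transcripts, had an ileum identity mean of 2.84 against −0.54 to 1.69 in the other colon libraries and a lipid absorption mean of 3.37 against 1.29 to 2.52. Without it the adjusted p was 0.0203 for ileum identity and 0.0145 for lipid absorption. Goblet cell and mucus genes rose (20 of 20 positive; 0.00641); CLCA1, a secreted protein of mucus, had 1.34 and TFF3, a mucus peptide, had 1.10, and with the smooth muscle mean as a covariate they had −0.054 and −0.21. Carbohydrate and peptide digestion (0.00345), bile acid and xenobiotic (0.0255), cell cycle (0.0462) and T and NK genes (0.0488) rose. With an estimated correlation all 14 calls were lost (adjusted p = 0.997 with an estimated correlation), and fry called none (0.938 to 1).

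**Figure D3:**
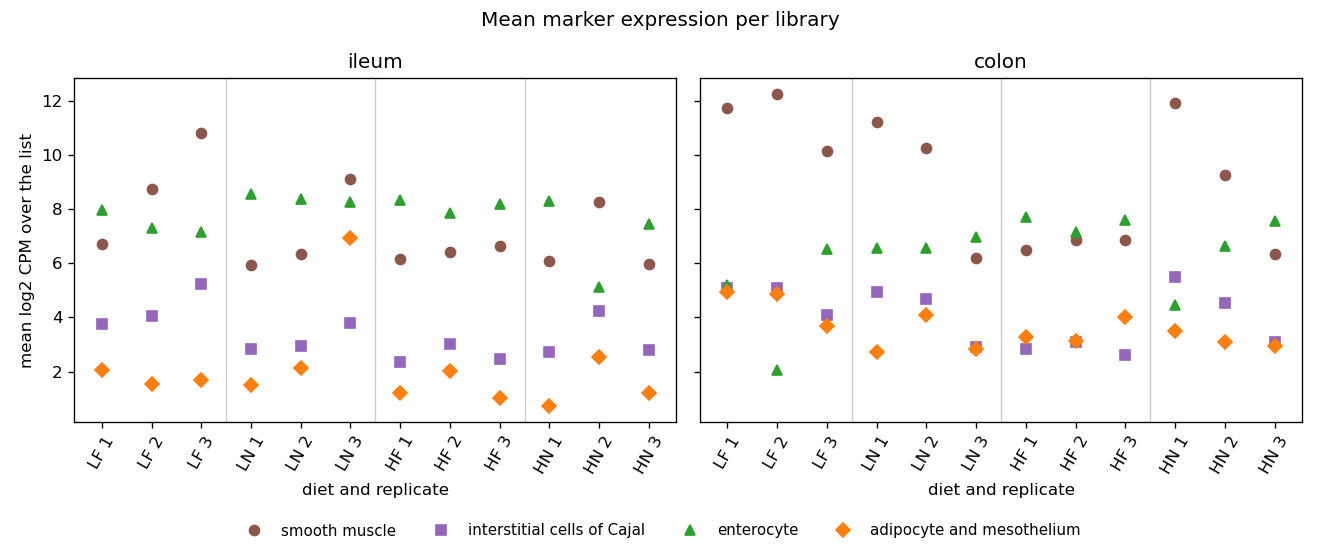
Mean log2 CPM (vertical axis) of the smooth muscle, interstitial Cajal cell, enterocyte and adipocyte markers in each library of the ileum (left) and colon (right), ordered by diet and replicate. The markers of smooth muscle varied between colon libraries of one diet, and ileum LN 3 stood apart with an adipocyte mean of 6.91.

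The smooth muscle, ileum identity, enterocyte, fatty acid oxidation, lipid absorption and fibroblast calls for fibre in the colon held in all 12 single omissions. Calls ended without HN 3 for enteric neurons (0.0619) and without HN 1 for carbohydrate and peptide digestion (0.0995). They ended without HN 3 (0.213) or LF 2 (0.708) for goblet cell and mucus genes and without HN 2 (0.0759), HN 3 (0.182), LN 2 (0.0587) or LF 2 (0.207) for bile acid and xenobiotic genes. The adipocyte call ended without HN 1 (0.0936), HN 2 (0.0538), HN 3 (0.0714), HF 2 (0.11), LN 2 (0.151), LN 3 (0.0579), LF 1 (0.08) or LF 2 (0.0681). The cell cycle call ended without HN 2 (0.154), HN 3 (0.691), HF 1 (0.143), HF 3 (0.114), LN 1 (0.0594), LN 2 (0.0639), LN 3 (0.0579) or LF 2 (0.559, direction reversed), and with RLE (0.0742). T and NK markers lost it without HN 2 (0.321), HN 3 (0.339), HF 3 (0.145), LN 1 (0.319) or LF 2 (0.788), and with RLE (0.0755). Matrix and integrin genes lost it without HN 2 (0.0835), HN 3 (0.313), HF 1 (0.173), LN 1 (0.0781), LN 2 (0.0835), LF 1 (0.0717) or LF 2 (0.128).

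No single colon gene passed for fibre with edgeR (692 of 15075 at an unadjusted p under 0.05, 21 with DESeq2, 4887 with voom). The nearest had log2 changes of 0.76 for MAP2K6, 1.15 for EPHX2, 1.03 for ATP8B3, 0.47 for VSIG10, 0.77 for CCDC28A, −2.05 for NR4A3, −1.46 for ITIH2, −0.65 for DDX5, −1.73 for IER3 and −0.95 for NAB2 (adjusted p = 0.836). CPS1, ASS1, ARG2, NAGS, AKT1 and PIK3CA had 2.33, −0.41, 0.09, 0.68, −0.03 and −0.55 and did not pass. The value of CPS1, which had 79 counts in HN 1, the library with ileum transcripts, ran from 0.85 to 3.30 over the single omissions. HF against LF called 0 colon genes with edgeR (3071 unadjusted), 288 with only the 6 libraries of both groups in the fit (8 higher and 280 lower), 1 with both marker covariates, 1037 with DESeq2 and 8186 with voom. The interaction called 0 with edgeR (2264 unadjusted, 65 with DESeq2, 3815 with voom, 1 with both marker covariates). UGCG, CD2AP and TRANK1 had interaction values of −1.37, −2.17 and −1.86, septin 12 of −5.22 and WFDC1 of 2.94 (adjusted p = 0.327); WFDC1 averaged 119 ± 34.7 CPM with LF, 23.7 ± 8.95 with LN, 22.8 ± 4.68 with HF and 35.1 ± 24.2 with HN.

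Of the lists not called in any of the 6 main comparisons, the smallest camera adjusted p was 0.325 for PI3K-Akt core, 0.149 for PI3K-Akt growth factors and receptors, 0.459 for arginine and urea cycle, 0.425 for short-chain fatty acid transport, 0.78 for antimicrobial defence, 0.153 for antioxidant response, 0.108 for unfolded protein response, 0.0733 for immediate early genes, 0.0948 for heat shock and 0.0637 for steroid response. Among the cell type markers it was 0.134 for goblet, 0.219 for enteroendocrine, 0.12 for tuft, 0.223 for stem and crypt, 0.0616 for neutrophil, 0.331 for mast cell, 0.165 for interstitial cells of Cajal, 0.842 for reproductive tract (ileum) and 0.633 for colon identity. Over the 267 tests camera called 60 at the preset correlation and 0 with an estimated one, fry called 0 by its directional p-value and 5 by its mixed p-value, and no called list had a median or mean of another sign than its test.

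Posterior HOX genes were higher in the colon, and genes of lipid and citrulline metabolism were higher in the ileum. HOXA13 averaged 54.3 ± 10.3 CPM in the colon and 0.00491 in the ileum (n = 12 each), HOXA11 42.1 ± 9.45 and 0.0129, HOXB13 26.2 ± 28.2 and 0.0185, HOXD10 40.9 ± 29.5 and 0.0491, and HOXD11 9.73 ± 5.66 in the colon with 0 counts in the ileum. The mucin MUC12 averaged 421 ± 323 CPM in the colon and 1.25 in the ileum, SPTSSB 49.6 ± 26.0 and 0.212, NXPE2 51.7 ± 44.5 and 0.286, and ABCA12 9.15 ± 10.7 and 0.00537. In the ileum CPS1 averaged 675 ± 328 CPM and in the colon 0.938, OTC 244 ± 135 and 0.646, MTTP, which loads lipoproteins with lipid, 393 ± 231 and 1.14, TFF2 317 ± 530 and 0.455, and SLC5A12 174 ± 161 and 0.811. MEP1A averaged 159 ± 301 and 0.600, ABCG8 72.6 ± 34.6 and 0.225, SDSL 66.5 ± 40.0 and 0.197, SLC2A2 39.8 ± 27.5 and 0.0606, and CYP2C36 16.4 ± 14.2 CPM in the ileum with 0 counts in the colon. The colon means of OTC, MTTP and MEP1A came mostly from colon HN 1, the library with ileum transcripts. They had 6.98, 10.7 and 6.78 CPM there, against at most 0.245, 0.820 and 0.442 in the other colon libraries. Each of these 19 genes passed (edgeR adjusted p between 7.9e-11 and 0.000419).

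In colon against ileum 4453 of 15675 genes passed, 1957 higher and 2496 lower in the colon, and 8370 passed with voom. Of the tested genes 229 had no overlap between the 12 colon and 12 ileum libraries, all of them called. Colon identity genes were higher in the colon (14 of 15 called; camera adjusted p = 1.04e-15), a call that held with an estimated correlation (adjusted p = 0.0117 with an estimated correlation). Ileum identity (18 of 19 called lower; 2e-17), lipid absorption (17 of 20; 2.05e-16) and carbohydrate and peptide digestion (22 lower and 2 higher of 27; 2.12e-16) were lower in the colon, with adjusted p = 0.0565, 0.3 and 0.123 with an estimated correlation. Arginine and urea cycle genes were lower (11 lower and 2 higher of 24; 0.00795), as were bile acid (0.000115), unfolded protein response (0.00617), T and NK (0.00942), plasma cell (0.0429) and enteroendocrine genes (0.0479). Matrix and integrin genes (14 of 40; 5.46e-06), smooth muscle (15 of 17; 6.93e-05), enteric neuron (0.00728), fibroblast (0.0115), cholesterol synthesis (0.0369) and adipocyte genes (0.0497) were higher. These 12 calls were lost with an estimated correlation (adjusted p = 0.815 to 0.832 with an estimated correlation), and the skeletal muscle list did not pass (0.936).

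Whether a diet effect differed between the tissues was tested directly, and no gene passed. For the fibre effect edgeR called 0 of 15675 genes (437 at an unadjusted p under 0.05, 5 with DESeq2, 439 with voom); RPS6KA5 had a difference of 0.89, BIRC7 4.20, SOWAHC 0.96, GNL3 −0.68 and G6PC 3.11 (adjusted p = 1). G6PC, glucose-6-phosphatase, averaged 31.0 ± 13.9 CPM with LF and 14.0 ± 3.84 with HF in the ileum, and 0.127 ± 0.135 and 2.34 ± 2.31 in the colon. For the NCG effect edgeR called 0 (469 unadjusted, 8 with DESeq2, 1 with voom). CDO1, cysteine dioxygenase, had −4.43 (adjusted p = 0.942), and LPGAT1, SLC38A3, PC and TYW1 had −0.66, −4.15, −2.36 and −1.22 (adjusted p = 1). CDO1 had 1188 counts in ileum LN 3 and 48 and 74 in LN 1 and LN 2, and PC had 5443 against 1133 and 703. Ileum LN 3 also stood apart in its adipocyte markers, with 1144 CPM of ADIPOQ.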

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

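The rule that picked the following 7 lists was set after the list results were seen, and so were the tests of the smooth muscle markers and of the ileum transcripts in colon HN 1. Of 181 tests of lists in the interactions and in the differences of a diet effect between tissues, 65 passed camera at the preset correlation and 0 passed after adjustment with an estimated correlation. The 7 lists below passed at the preset correlation and also had an unadjusted p under 0.05 with an estimated correlation.

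The fibre effect was more positive in the colon than in the ileum for lipid absorption and lipoproteins (20 of 20 genes, median difference 0.89, adjusted p = 9.98e-11; estimated correlation p = 0.0201, adjusted 0.759). The same direction held for fatty acid oxidation and PPARA targets (24 of 26 genes, median 0.54, adjusted p = 3.30e-09; estimated correlation p = 0.0264, adjusted 0.815). Ileum identity genes differed likewise (14 of 19 genes, median 2.32, adjusted p = 8.15e-07; estimated correlation p = 0.0179, adjusted 0.759), and so did carbohydrate and peptide digestion (22 of 27 genes, median 0.99, adjusted p = 3.40e-06; estimated correlation p = 0.0383, adjusted 0.823). Ileum transcripts in colon HN 1 enter these differences except that of fatty acid oxidation, where its mean of 5.66 was the lowest of the high-fibre colon libraries. Ileum HN 2 had the lowest ileum means of lipid absorption (3.36 against 5.77 to 8.29), fatty acid oxidation (4.83 against 5.49 to 6.53), ileum identity (4.26 against 6.11 to 7.92) and carbohydrate digestion (5.0 against 5.99 to 7.44), and also enters them. Interferon-stimulated genes had a negative interaction in the colon (27 of 30 genes, median −1.03, adjusted p = 3.54e-06; estimated correlation p = 0.0471, adjusted 0.823). Bile acid and xenobiotic genes had a negative interaction in the ileum (16 of 19 genes, median −0.996, adjusted p = 0.000192; estimated correlation p = 0.042, adjusted 0.823). The NCG effect was lower in the colon than in the ileum for adipocyte and mesothelium markers (8 of 9 genes, median −2.76, adjusted p = 0.000385; estimated correlation p = 0.045, adjusted 0.823), and the adipocyte values of ileum LN 3, with a marker mean of 6.91 against 0.71 to 2.54 in the other ileum libraries, enter this difference.

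The lower smooth muscle markers with fibre in the colon may reflect how deep the gut wall was sampled. Over the 12 colon libraries, with each diet's mean removed, the smooth muscle mean moved with the mean of the interstitial Cajal cell markers, another cell type of the muscle wall (Pearson's r = 0.981, permutation p = 1e-05, the smallest these permutations can give, adjusted p = 6.00e-05 over 6 relations; Spearman's rho = 0.951, permutation p = 2.00e-05; r = 0.950 without the 2 most distant libraries). It moved with fibroblast (r = 0.869) and enteric neuron markers (r = 0.811) and against enterocyte (r = −0.634), goblet cell and mucus (r = −0.652) and T and NK markers (r = −0.718), in line with varying shares of wall and mucosa within a diet. The mean over the smooth muscle markers itself was 7.95 ± 2.21 in the 6 high-fibre and 10.29 ± 2.17 in the 6 low-fibre libraries (exact permutation p = 0.0952, adjusted p = 0.495 over 52 such tests). An effect of fibre on the muscle wall itself stays open and was not tested apart from the sampled depth.

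The ileum transcripts in colon HN 1 are consistent with carry-over of ileum RNA. In this library 22 of 25 ileum genes (88%) reached 0.5% of their ileum mean, at a median of 2.19% (quartiles 1.17% and 3.37%), while the share was 0% to 20% in the other colon libraries. The 25 genes were chosen as abundant and even in the ileum and with a colon median near 0. Low shares in most of the other colon libraries therefore follow from the choice. APOB had 718 counts (48.7 CPM, 3.90% of its ileum mean), OTC stood at 2.86% and MTTP at 2.73%. Other ileum genes examined differed more, with GATA4 at 0.72%, CPS1 at 0.80% and FABP2 at 10.4%. Whether the RNA entered at dissection, at library preparation or on the sequencer, or whether this colon sample held ileum-like cells, is not decided by these values. No biological explanation was tested.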

How the results depend on the processing

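The fits with a length trend removed, with marker covariates, without the ileum libraries high in FABP6 and without the 2 colon libraries lowest in enterocyte markers were chosen after the data were seen. Where a count or direction changed the cause was not tested, except that fits with fewer libraries also have less information by construction. With RLE the counts were 889, 640 and 308 for NCG, LN against LF and HN against LF in the ileum, 4402 for colon against ileum and 0 elsewhere, and with no filter 781, 583, 255, 4272 and 0. Over all alternatives, counts of genes or lists stayed within 1.5 times of the reported value in 312 cases and moved further in 64. A count of 0 that stayed 0 is among the 312, so this total says little about the counts above 0. Of the 12 single omissions in the ileum the count moved further in 3 for NCG, 3 for LN against LF and 10 for HN against LF. Named genes kept direction and call in 4722 cases, lost a call in 332, gained one in 211 and turned direction in 106, the last only in genes that had not passed, and list calls were kept in 713 cases, lost in 245 and reversed in 2. The 4722 cases include genes that passed in neither fit. At the lowest total of 11951729 counts a count of 0 allows 0.251 CPM, so lower levels could not be told from 0. A transformation of FPKM was foreseen only for a table without counts and was not run.

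DESeq2 called 1 gene for fibre in the ileum (0 higher, 1 lower), 1739 for NCG (1290, 449), 20 for the interaction (10, 10), 12 for HF against LF (2, 10), 1573 for LN against LF (1194, 379) and 896 for HN against LF (769, 127). In the colon it called 21 (10, 11), 465 (255, 210), 65 (39, 26), 1037 (235, 802), 615 (329, 286) and 183 (109, 74) in the same order. For the differences between tissues it called 5 for fibre (4, 1) and 8 for NCG (4, 4).

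Voom with quality weights called 1835 genes for NCG in the ileum (1192 higher, 643 lower), 1 for the interaction (0, 1), 1727 for LN against LF (1297, 430) and 495 for HN against LF (476, 19). In the colon it called 4887 for fibre (2134, 2753), 4242 for NCG (2487, 1755), 3815 for the interaction (2073, 1742), 8186 for HF (4002, 4184), 5850 for LN (3123, 2727) and 6922 for HN against LF (3574, 3348). It called 8370 for colon against ileum (3962, 4408), and 439 (273, 166) and 1 (0, 1) for the differences of the fibre and NCG effects. Directions turned for NAGS (−0.18) and ASS1 (0.40) with NCG in the ileum and for NAGS (−0.39) and OTC (−0.11) in HN against LF there. In the colon they turned for CPS1 with fibre (−1.50), for ASS1 (−0.16), CPS1 (−1.27) and NAGS (0.32) with NCG, and for ASS1 (−0.71) and CPS1 (−2.76) in HN against LF.

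With only the 2 compared groups in the fit 0 genes passed for LN and for HN against LF in the ileum, and 288 for HF against LF in the colon (8 higher, 280 lower). Camera with an estimated correlation called 0 of the planned list tests and fry 0. With the length trend removed HN against LF in the ileum called 189 (187, 2), OTC turned with NCG in the ileum (0.10), and CPS1 (−0.13) and NAGS (0.027) turned with NCG in the colon.

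The smooth muscle covariate turned CPS1 with fibre (−0.31), NAGS with NCG (−0.076) and NAGS in HN against LF (−0.34) in the ileum. In the colon it turned ARG2 (−0.42), NAGS (−0.33), PIK3CA (0.15), CLCA1 (−0.054) and TFF3 (−0.21) with fibre, CPS1 with NCG (−0.60), and ARG2 (−0.29), ASS1 (−0.10) and NAGS (−0.36) in HN against LF. With smooth muscle and enterocyte covariates the counts in the ileum were 1736 for NCG (1290 higher, 446 lower), 1067 for LN (952, 115) and 88 for HN against LF (84, 4). In the colon they were 1814 for NCG (1224, 590), 1 for the interaction (1, 0), 1 for HF (0, 1), 1571 for LN (1137, 434) and 2098 for HN against LF (1299, 799). Both covariates turned NAGS (0.26), CCR7 (−0.79), CD4 (−0.36), CD5 (−0.22), CD79B (−0.81), PCNA (−0.0038) and PLN (0.33) with fibre and OTC (0.11) with NCG in the ileum. In the colon they turned ARG2 (−0.43), NAGS (−0.26), PIK3CA (0.44), CLCA1 (−0.22) and TFF3 (−0.26) with fibre, CPS1 with NCG (−0.52), and ARG2 (−0.41), ASS1 (−0.23) and NAGS (−0.62) in HN against LF.

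Without the ileum libraries high in FABP6, HN against LF called 0, and NAGS (0.28) and PIK3CA (−0.28) with fibre and ASS1 with NCG (0.71) and in HN against LF (0.15) turned. Without the 2 colon libraries lowest in enterocyte markers NCG called 464 (446 higher, 18 lower) and LN against LF 282 (273, 9), and AKT1 with fibre (0.016), CPS1 with NCG (−1.26) and CPS1 in HN against LF (−0.20) turned.

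Without 1 library, counts in the ileum ran from 514 (510 higher, 4 lower; without HF 1) to 958 (783, 175; without LN 1) for NCG, from 133 (130, 3; without LF 2) to 748 (717, 31; without HN 2) for LN against LF and from 0 (without HN 2) to 480 (471, 9; without LN 3) for HN against LF. In the colon they ran from 0 to 292 (286, 6; without LF 2) for NCG and from 0 to 11 (9, 2; without HN 1) for LN against LF. The adjusted p of the cell cycle list with fibre in the colon ran from 0.000281 (without LF 3) to 0.691 (without HN 3), and that of junctions in HN against LF of the ileum from 5.71e-06 (without HN 1) to 0.975 (without HN 2). Log2 changes that turned with 1 library left out had these ranges. With fibre in the ileum they were −0.26 to 0.31 for CPS1, −0.49 to 0.21 for NAGS, −0.28 to 0.49 for OTC, −0.18 to 0.29 for PIK3CA and −1.95 to 0.78 for ASS1. With NCG in the ileum they were −0.42 to 0.28 for NAGS and −0.54 to 0.29 for OTC, and in HN against LF −0.030 to 0.55 for ARG2, −0.91 to 0.49 for NAGS, −0.82 to 0.72 for OTC and −3.22 to 0.57 for ASS1. With fibre in the colon they were −0.11 to 0.018 for AKT1, −1.06 to 0.062 for PIK3CA and −0.078 to 0.32 for ARG2. With NCG in the colon they were −1.29 to 1.52 for CPS1, −0.062 to 0.33 for ARG2 and −0.42 to 0.49 for NAGS, and in HN against LF −0.26 to 2.95 for CPS1, −0.44 to 1.79 for PIK3CA, −0.14 to 0.65 for ARG2 and −0.58 to 0.60 for ASS1. Among the same 7 genes, others kept their direction and moved over 1.5 times. In the ileum these were AKT1 with fibre (−0.16 to −0.047), CPS1 (−0.94 to −0.36) and ASS1 (−2.10 to −0.21) with NCG, and CPS1 in HN against LF (−1.20 to −0.047). In the colon they were NAGS (0.43 to 1.32), ASS1 (−0.84 to −0.10) and CPS1 (0.85 to 3.30) with fibre, PIK3CA (0.61 to 1.73) and ASS1 (0.26 to 1.09) with NCG, and NAGS (0.0034 to 1.80) and AKT1 (−0.40 to −0.15) in HN against LF.

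The labels do not say whether libraries of one number come from the same sow, and their correlations do not settle it. No correlations between unlike numbers in ileum and colon stand beside them for reference, so a shared sow is not excluded. Libraries with one number in ileum and colon of a diet had correlations of −0.368 to 0.307, with 5 of 12 above 0.1, and libraries with one number in different diets went both ways (−0.532 to 0.714 in the ileum, −0.521 to 0.823 in the colon). With a replicate block the ileum counts were 665 for NCG, 460 for LN and 0 for HN against LF, 3001 for colon against ileum, 0 in the colon and 59 list calls. The block turned CPS1 (−0.085) and OTC (−0.062) with fibre, NAGS (−0.015) with NCG, and NAGS (−0.17) and OTC (−0.13) in HN against LF, all in the ileum.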

Other observations

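The enrichment tests, the tests of gene length alone, of marker covariates and of the shared difference in the colon for the NCG genes, and the tests of zinc finger genes were chosen after the ileum result was seen.

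Zinc finger genes stood out among the ileum genes higher with NCG. Of 350 tested genes named or described as zinc finger proteins, most of them DNA-binding regulators of transcription, 72 were higher and 0 lower, against 19.0 expected (Fisher's exact p = 2.50e-23). This test, like the other enrichment tests, counts genes that move together as independent, so its p-value does not measure the spread between libraries. The 350 genes had a median length of 5034.5 bases, against 3721 for all tested genes. With NCG in the colon 280 of 355 were positive, against 56.7% of all genes, and edgeR called none. ZNF146, ZNF181, ZNF644 and ZNF24 rose by 1.53, 1.5, 1.32 and 1.18 on the log2 scale, while the median over all 350 was 0.20 and 222 were positive. The pathway named Herpes simplex virus 1 infection was the 1 of 322 pathways that passed (65 genes against 15.4 expected, Fisher's exact adjusted p = 1.62e-22), and 48 of the 65 are zinc finger genes, so its name does not describe them. Genes of ubiquitin-dependent protein breakdown were also over-represented (30 against 12.5 expected, adjusted p = 0.0119), for example CUL5 with 1.76, USP16 with 1.39 and UBR1 with 0.93. With the length trend removed this was lost (22 against 10.2, adjusted p = 0.172). The PI3K-Akt pathway of the annotation held 19 higher genes against 14.5 expected (adjusted p = 1).

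Among the 65 ileum genes lower with NCG, parts of the spliceosome were over-represented (9 against 0.635 expected, Fisher's exact adjusted p = 2.10e-06). SNRPF fell by 0.72, SF3B5 by 0.71, LSM7 by 0.65, SNRPE by 0.60, MAGOH by 0.59, RBM8A by 0.47, CTNNBL1 and PUF60 by 0.44, and BUD31 by 0.35. With the length trend removed the spliceosome call was lost (4 against 0.84, adjusted p = 0.609), so a length trend and NCG cannot be told apart there. The lower genes also numbered 4 without HF 1 and 175 without LN 1. With the trend removed the Herpes simplex pathway stayed over-represented among the higher genes (59 against 12.9 expected), and 2 processes passed that had not passed with the trend in place. These were regulation of mitotic spindle assembly (7 against 0.687, adjusted p = 0.003, before 0.054) and protein deubiquitination (12 against 3.02, adjusted p = 0.0305, before 0.0534).

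The ileum genes higher with NCG were long, and the libraries with NCG had a steeper trend of expression with gene length (exact permutation p = 0.00433 in the ileum and 0.0909 in the colon), so a technical trend was weighed. With the length trend removed 77.9% of the 819 genes were still called higher, with trends on length, genomic span and local gene density removed together 70.9%, and with smooth muscle and enterocyte markers as covariates 98.0%, and their median log2 change went from 1.17 to 1.01, 0.95 and 1.20, which argues against each of these as the whole cause. In the colon 811 of 814 of these genes had positive changes with NCG, against 56.7% of all genes. Their mean was higher in the colon libraries with NCG (exact permutation p = 0.0216), which a difference shared by both tissues would give. It was 5.04 in LF 2 without NCG, however, and 4.18 in HN 3 with NCG. The length trend was not removed here. Across genes the NCG effect in the colon went with length (Spearman's rho = 0.360, against 0.281 in the ileum). A shared effect of NCG and a shared length trend thus cannot be told apart in the colon. The test of a different NCG effect in the tissues called 0 genes with edgeR (469 unadjusted, 8 with DESeq2, 1 with voom). This does not show that the effects are alike. For the lower oxidative phosphorylation genes, which are short (median 933 bases), 48.4% of the median ileum change was left with the length trend removed (−0.38 to −0.19), so a length trend and NCG cannot be told apart there. GC content could not be tested without the genome sequence, and a batch or a difference in RNA quality that follows NCG has no label and stays open beside an effect of NCG itself.

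Other divisions of the same libraries into groups of the same sizes show what chance gives. For NCG in the ileum 1 of 60 splits, the real one, gave as many as 884 genes, and the highest other gave 2. This share is under 0.05 and is the smallest that these splits can give, so chance is made unlikely and not excluded. The other splits mix libraries with and without NCG, which adds any NCG difference to the spread within groups. The size of the gap between 884 and 2 therefore says little. For colon against ileum 1 of 30 splits, the real one, gave as many as 4453 genes, against 0 in the others. Those others mix the tissues, which puts the tissue difference into the spread within groups, so their 0 calls say little about chance. Where the real division called 0 genes, each split has at least as many by construction, so the splits say nothing about chance there. The highest other counts were 21 for fibre and 1 for the interaction in the ileum, and 2065 for fibre, 5255 for NCG and 4924 for the interaction in the colon. They were 0 for the difference of the fibre effect between tissues and 185 for that of the NCG effect. For 3 libraries against 3 the 10 splits are too few for a share under 0.05. Real value and highest other were 0 and 0 for HF against LF in the ileum, 656 and 0 for LN against LF (1 split) and 284 and 0 for HN against LF (1 split), and in the colon 0 and 0, 0 and 0, and 0 and 5995. The split with 5995 genes set HN 1, LF 1 and LF 2 against HN 2, HN 3 and LF 3, another with 901 set HN 1, HN 2 and LF 2 against HN 3, LF 1 and LF 3, and such counts point to a structure of the colon libraries other than diet.

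Some libraries are given as values only. FABP6, the ileal bile acid binding protein, stood at 8171 CPM in ileum LF 1, 4229 in HF 2 and 767 in HN 2. The enterocyte marker mean (log2 CPM) was lowest in the colon libraries LF 2 (2.06) and HN 1 (4.46).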
